A study of Mus musculus with 26 samples.

How the data were processed

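The series holds processed values for 12 tumour and 14 sorted-cell libraries of KPC mice, and nothing was aligned or counted anew. Per the submitters' processing notes, reads were handled with TopHat2, STAR and limma against the mouse assembly mm10; neither their versions nor the step each tool served is given. Per the labels, tumours were kept in RNAlater, RNA was extracted with RNeasy and libraries were made with a stranded total RNA kit after removal of ribosomal RNA, then run on 1 lane of an Illumina HiSeq instrument (100 bp, paired ends). Sorted-cell libraries were made with either of 2 kits (Illumina TruSeq or NuGEN, which one per library is not given) and were run in 4 lanes. Treated animals are labelled with 14 days of GS9820, and no day is given for vehicle animals. The labels name the sorted cells as PMN, also marked "low", and as monocytes, also marked "high".

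The deposited values are log2 expression values, named log2 RPKM by the authors. Within a set the libraries share nearly 1 distribution: sorted values differ between libraries by at most 0.861 in tumours and 1.72 in sorted cells, with a median difference of 0 and 0.00363. After reversal of the log2 the sums per library are 1552390 to 1552450 and 1429080 to 1430330. After multiplication by gene length they are 5950820 to 6504750 and 5267110 to 6331270. The values are therefore not RPKM in scale and are called deposited log2 values here. Sequencing depth and counts could not be recovered, so tests on counts were not run. In PMN the most abundant genes hold the same value in every library, a result of the shared distribution.

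Symbols, types and positions were taken from GENCODE M21 (GRCm38). Of 16322 tumour and 14131 sorted-cell genes, 16039 and 13886 identifiers were matched and 283 and 245 had no symbol. Genes of chromosomes X and Y were not analysed here, and neither was the sex of the mice. No pair of libraries was identical (0 pairs), and correlations between libraries ran from 0.630 to 0.945 in tumours and from 0.784 to 0.984 in sorted cells.

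Genes were kept at a deposited log2 value of at least 0 in at least 5 tumour or 3 sorted-cell libraries, which left 16296 and 13968. Differences were tested with limma 3.58.1 (lmFit, eBayes with the mean trend; two-sided) in R 4.3.3 with statmod 1.5.0, with Benjamini-Hochberg adjustment within each of 5 comparisons and a threshold of adjusted p 0.05. Tumours formed 1 fit, and the 14 sorted-cell libraries another with 4 groups. Comparisons were treated against vehicle in tumours, in PMN and in monocytes, monocytes against PMN in vehicle mice, and the difference of the treatment effects. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

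Before the data were examined, 46 gene lists were fixed, 22 of them markers of cell types, and lists with at least 5 kept genes were tested (40 in tumours, 39 in sorted cells). Lists with fewer kept genes were left out of tests: NK and cytotoxic lymphocyte, mast cell and basophil, eosinophil, platelet and megakaryocyte, and skeletal muscle in tumours, and platelet and megakaryocyte, acinar, islet, skeletal muscle, smooth muscle and hepatocyte in sorted cells. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and beside it with a correlation estimated per list and with fry. Members were also adjusted over their list alone. The difference of list means per library was tested by exact two-sided permutation over all splits of the libraries.

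Genes named in the text are the 12 largest rises and 12 largest falls past the threshold with a higher group mean of at least 1, leaving out predicted or unnamed models and small RNA genes. Where fewer than 10 genes passed, genes of smallest unadjusted p are given as values to make 10. Of each list up to 4 members past the threshold are named, or else up to 2 of smallest p, and for other cell types the members of highest mean. Pik3ca, Pik3cb, Pik3cd and Pik3cg were looked up in every comparison.

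The pipeline was tested on simulated data made with the same group sizes, with 200 changed genes, 50 each at folds of 1.5, 2, 4 and 8. The share recovered at these folds was 2, 40, 82 and 92 percent in tumours and 14, 56, 82 and 94 percent in PMN. It was 26, 50, 82 and 92 percent in monocytes, 20, 42, 80 and 90 percent for monocytes against PMN and 14, 20, 76 and 82 percent for the difference of effects. Calls among unchanged genes numbered 8, 7, 8, 3 and 3, and a lowered list of ribosomal proteins was found in all 5 with 0 other lists called. The simulated genes varied independently of each other, so this does not show how camera behaves on lists of correlated genes.

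Alternatives to these choices were no filter or a stricter one (a value of at least 2), log2 of the value plus 1, quantile normalization, centring on the median, eBayes without the trend or robust, array quality weights, each library left out in turn, a block of the shared replicate number, each cell type fitted alone, and the acinar list mean as a covariate. Chosen after the values were seen were the islet list mean as a covariate, leaving out both tumours least correlated with their groups, protein-coding genes only, leaving out a block of gene copies on chromosome 4, and, for lists, the acinar and islet covariates. For the sorted cells the estimation of array weights stopped before its tolerance was reached.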

Results

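RNA was sequenced from KPC mice, a genetically engineered model of pancreatic ductal adenocarcinoma, that had received vehicle or GS9820, an inhibitor of the p110δ catalytic subunit of phosphoinositide 3-kinase (PI3K) given for 14 days. Whole tumours made up 12 libraries, 7 from vehicle and 5 from GS9820-treated mice. Myeloid cells sorted from the spleen made up 14 libraries, with 3 vehicle and 4 treated libraries each for polymorphonuclear cells (PMN) and for monocytes. Each tumour library held a deposited log2 expression value for 16322 genes and each sorted-cell library for 14131. The values had nearly the same distribution in every library of a set, so sequencing depth per library could not be recovered and is unknown. All changes below are differences of deposited log2 values, given with their standard error (SE), and group means are given with their standard deviation (SD).

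The tumour comparison asked how a pancreatic tumour as a whole, with its inflammatory and metabolic transcripts, differed after the inhibitor. Genes of hormone-producing cells were the largest rises. Pyy, which encodes peptide YY (ENSMUSG00000017311, chromosome 11, 102106676 to 102107832), rose by 5.20 ± 1.16, from 1.96 ± 2.73 (SD, n = 7) in vehicle tumours to 7.16 ± 1.13 (SD, n = 5) in treated tumours (limma, adjusted p = 0.04). Chgb and Chga, which encode granins of endocrine secretory granules, rose by 4.73 ± 1.10 and 4.17 ± 0.90. Ppy (pancreatic polypeptide) rose by 4.69 ± 1.10 and Ghrl (ghrelin) by 3.86 ± 0.70. The neutrophil-attracting chemokine gene Cxcl3 (ENSMUSG00000029379, chromosome 5, 90786103 to 90789600) fell by 4.17 ± 0.70, from 2.97 ± 1.41 (SD, n = 7) to -1.20 ± 1.06 (SD, n = 5; limma, adjusted p = 0.0189).

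Outside the endocrine genes, Hal, for histidine breakdown, rose by 4.07 ± 0.74 and the carboxylesterase gene Ces1d by 3.89 ± 0.74. Pipox, for pipecolate oxidation, rose by 3.79 ± 0.59 and the alcohol dehydrogenase gene Adh1 by 3.64 ± 0.83. The C-type lectin genes Cd209g and Cd209f rose by 4.01 ± 0.62 and 3.86 ± 0.49, and Tnxb, a matrix glycoprotein of the tenascin family, by 3.68 ± 0.55. Among the 12 largest falls, Cdh13, which encodes a cadherin anchored to the membrane without a transmembrane domain, had the highest vehicle mean. It changed by -2.83 ± 0.48 and averaged 6.17 ± 0.86 (SD, n = 5) in treated tumours. Dynap (-4.62 ± 0.78), the long noncoding RNA Wincr1 (-3.72 ± 0.59) and Klhl1 (-3.71 ± 0.78) had the largest falls beside Cxcl3. Irx3os (-3.67 ± 0.86) overlaps the gene Irx3. Further falls were those of the YAP target Ankrd1 (-2.78 ± 0.52), the lymphocyte inhibitory receptor Tigit (-2.58 ± 0.58) and Pbp2 (-2.57 ± 0.52). The steroid reductase gene Srd5a1 (-2.55 ± 0.40), Gpihbp1 (-2.54 ± 0.58) and the protease inhibitor Serpinb2 (-2.48 ± 0.46) fell as well.

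**Figure D1:**
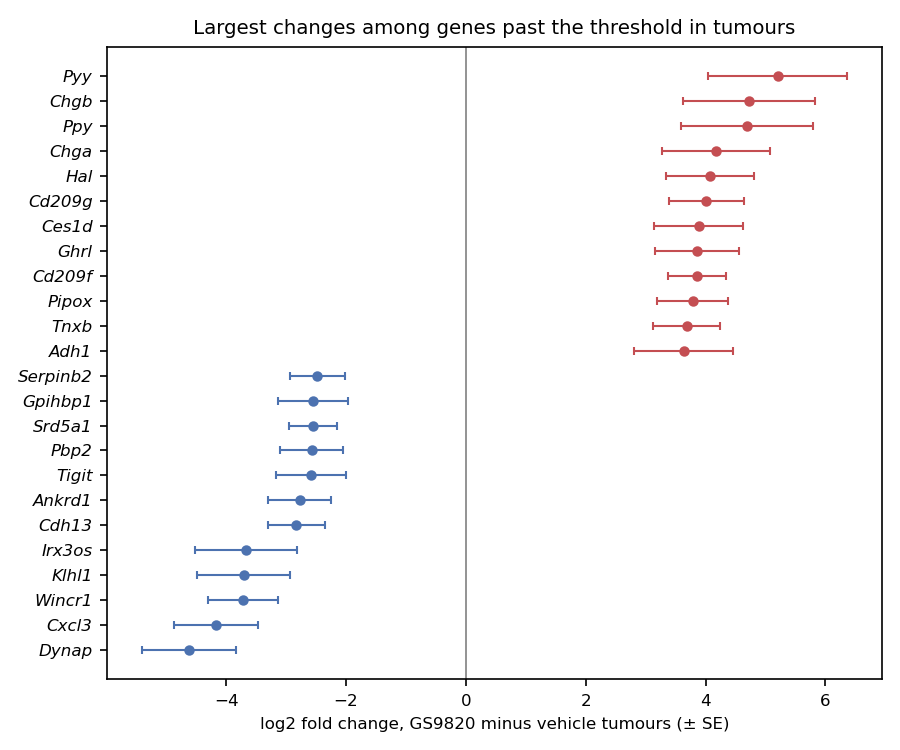
The 12 largest rises and 12 largest falls in tumours among named genes past the threshold; the x axis gives the log2 fold change, GS9820 minus vehicle, each point is the fitted change and each bar its SE. The changes range from -4.62 for Dynap to 5.20 for Pyy.

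Of 23 measured genes of the glycolysis and hypoxia list, 8 fell over all genes tested and 18 when adjusted over the list alone, and 21 had a negative change. The median change was -1.20. Pfkl, the liver-type phosphofructokinase, changed by -1.21 ± 0.23, the glucose transporter Slc2a1 by -1.34 ± 0.27. The glycolytic mutase Pgam1 changed by -1.54 ± 0.32 and the hypoxia-induced Ankrd37 by -2.03 ± 0.43. The list passed camera with a preset correlation (adjusted p = 6.8e-10) but not with an estimated one (adjusted p = 0.465 with an estimated correlation). The exact permutation test of its mean per library gave two-sided p = 0.00253 (adjusted p = 0.0505 over 40 lists). Fatty acid oxidation had 0 of 16 genes past the limma threshold over all genes, 3 rising when adjusted over the list alone, and a median change of 0.51 (adjusted p = 0.465 with an estimated correlation). Ucp2 stood at 0.89 ± 0.23, not past the threshold. The list means were 6.61 and 5.68 in treated tumours 1 and 3, where those of hepatocyte markers were 6.48 and 11.23, and 4.58 to 4.79 in the other treated tumours, against 4.27 to 4.86 in vehicle. Vehicle tumour 4, with a hepatocyte mean of 5.64, stood at 4.68 for fatty acid oxidation. Without treated tumour 1 the median for the list fatty acid oxidation in tumours was 0.18. Of 14 genes of fatty acid synthesis and lipid storage, Acacb, an acetyl-CoA carboxylase, rose by 1.61 ± 0.34 and the other 13 did not pass. The median of this list was -0.06 while its mean (0.14) and its test were above 0 (camera, adjusted p = 0.5; 2 genes rose when adjusted over the list alone, adjusted p = 0.731 with an estimated correlation). Of 10 adipocyte markers, 0 passed over all genes and 7 rose when adjusted over the list alone (median 1.69; adjusted p = 0.465 with an estimated correlation). Car3 stood at 5.27 ± 1.34 and the adipokine gene Adipoq at 4.16 ± 1.13. The mitochondrially encoded genes had a median change of 0.68, with 0 of 13 past the threshold over all genes and 1 rising when adjusted over the list alone (adjusted p = 0.465 with an estimated correlation). Amino acid response genes of the ATF4 list had a median of -0.38, with 0 of 18 past the threshold and 1 falling when adjusted over the list alone (adjusted p = 0.586 with an estimated correlation).

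In the islet list 4 of 16 genes rose over all genes (Chga, Chgb, Ppy and G6pc2, the last by 3.38 ± 0.80) and 13 when adjusted over the list alone, with a median change of 3.77 (adjusted p = 0.465 with an estimated correlation; exact permutation p = 0.00631, two-sided, adjusted p = 0.0842). The members with the highest mean level, Ins1 for insulin at 5.38 ± 1.33 and Gcg for glucagon at 5.57 ± 1.57, did not pass (limma, adjusted p = 0.0549 and 0.0712). Of 23 acinar genes all 23 were higher in treated tumours on average and 1 rose, the acinar transcription factor Nr5a2 by 2.28 ± 0.41, over all genes and also when adjusted over the list alone. The mean change of the list was 2.39 (adjusted p = 0.465 with an estimated correlation). The list means per library ran from 0.63 to 5.42 in vehicle and from 4.64 to 6.99 in treated tumours for islet, and from 2.27 to 9.79 and 5.45 to 9.97 for acinar genes. Ductal and carcinoma epithelium had 0 of 18 genes past the threshold, over all genes or when adjusted over the list alone, and a median of 1.02 (adjusted p = 0.594 with an estimated correlation), and without vehicle tumour 1, where the list no longer passed camera, the median was 0.52. Hepatocyte markers had 0 of 8 past the threshold by either adjustment, and a median of 2.71 (adjusted p = 0.465 with an estimated correlation). Without treated tumour 3 the median was 0.89 and the list no longer passed camera. That tumour's list mean was 11.23.

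**Figure D2:**
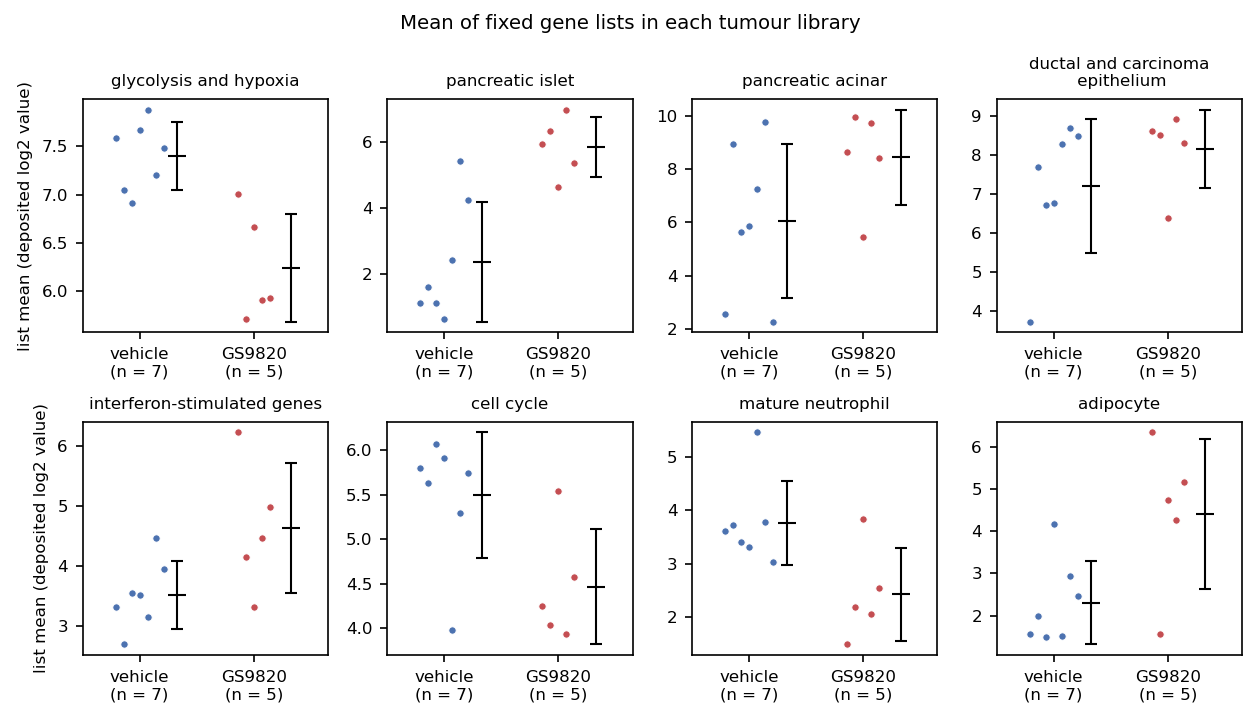
Mean deposited log2 value of 8 fixed gene lists in each tumour library; points are libraries (7 vehicle, 5 GS9820) and the bars beside them give the group mean ± SD. Glycolysis and hypoxia lie lower and islet genes higher in treated tumours, while the acinar range of vehicle tumours, 2.27 to 9.79, spans most of the treated values.

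Of 13 mature neutrophil markers, 0 passed over all genes and 6 fell when adjusted over the list alone (median -1.37; adjusted p = 0.465 with an estimated correlation; exact permutation p = 0.0202, two-sided, adjusted p = 0.166). The decoy receptor gene Il1r2 stood at -2.74 ± 0.66 and Trem1 at -1.81 ± 0.50. Of 22 innate inflammatory cytokines and mediators, 1 fell, Cxcl3, by either adjustment, and the related Cxcl2 stood at -2.21 ± 0.68 without passing. Interferon-stimulated genes were higher in all 25 of 25 measured members on average. Stat2 rose by 1.43 ± 0.28, the RNA sensor Ddx58 by 1.26 ± 0.27 and Irgm1 by 1.08 ± 0.25. These 3 rose over all genes and 6 when adjusted over the list alone, with a median of 1.06 (adjusted p = 0.465 with an estimated correlation; exact permutation p = 0.0354, two-sided, adjusted p = 0.177). The interferon list mean was 6.24 in treated tumour 1, 3.32 to 4.98 in the other treated tumours and 2.69 to 4.47 in vehicle. MHC class II (0 of 10 past the threshold), T cell (0 of 16) and B cell genes (0 of 15, 1 rising when adjusted over the list alone) had medians of 1.10, 1.18 and 1.07, and no member of these lists had a negative change (adjusted p = 0.465, 0.515 and 0.58 with an estimated correlation). The T and B cell list means were highest in treated tumour 4 (4.41 and 5.92). Those of vehicle tumour 7 (3.25 and 4.75) lay above the other treated tumours. Plasma cell markers (median 1.34, 0 of 10 and 1 rising when adjusted over the list alone; adjusted p = 0.465 with an estimated correlation) included Irf4 at 1.80 ± 0.51. Medians were 0.38 for monocyte (0 of 14), 0.81 for dendritic cell (0 of 9, 1 rising when adjusted over the list alone) and 0.41 for NF-kB feedback genes (0 of 14), whose adjusted p was 0.585, 0.465 and 0.465 with an estimated correlation. Arg1, an effector of suppressive myeloid cells, stood at -2.34 ± 0.77. Pik3cd, which encodes the subunit that the drug inhibits, stood at 0.70 ± 0.34. Pik3cg stood at 0.52 ± 0.27, Pik3ca at -0.40 ± 0.23 and Pik3cb at -0.36 ± 0.22. The test gave 0 of the 4 past the limma threshold and 0 of 4 at an unadjusted p under 0.05.

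All 32 of 32 cell cycle genes had a negative change (median -1.07). Of these 1 fell over all genes, the replication licensing factor Mcm6 (-1.45 ± 0.33), and 15 when adjusted over the list alone (adjusted p = 0.465 with an estimated correlation). In the heat shock list 2 of 11 fell, Hsp90aa1 (-1.34 ± 0.25) and Hsph1 (-0.90 ± 0.21), and 7 when adjusted over the list alone (median -0.63; adjusted p = 0.465 with an estimated correlation). Its exact permutation p of 0.00126 (two-sided, adjusted p = 0.0505) is the smallest that the 792 splits of the 12 tumours can give. Ribosomal protein genes had a median of -0.46 with 0 of 28 past the threshold by either adjustment (adjusted p = 0.465 with an estimated correlation). Among 15 endothelial genes 2 rose, the VEGF receptor Kdr by 1.06 ± 0.23 and Egfl7 by 1.02 ± 0.22, and 9 when adjusted over the list alone (median 0.55; adjusted p = 0.465 with an estimated correlation). Of 20 fibroblast and matrix genes Dcn rose by 1.61 ± 0.33 and Dpt by 1.99 ± 0.44, by either adjustment, while Col1a1 stood at 0.32 ± 0.50. The list did not pass camera (median 0.19; adjusted p = 0.0533, and adjusted p = 0.662 with an estimated correlation). Smooth muscle genes had a median of 0.84, with 0 of 9 past the threshold and 1 rising when adjusted over the list alone (adjusted p = 0.465 with an estimated correlation). Of 19 immediate early genes Zfp36 rose by 1.16 ± 0.25, by either adjustment, with a list median of 0.01 (camera, adjusted p = 0.164, and adjusted p = 0.585 with an estimated correlation).

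Other fixed groups stayed near 0 or did not pass camera in tumours. Matrix proteases and inhibitors had a median of -0.73 with 0 of 16 past the threshold (Plaur, the urokinase receptor gene, at -1.34 ± 0.38; Mmp8 at -1.98 ± 0.63), and myeloid suppressor effectors one of -0.27 (0 of 13) and innate cytokines one of -0.28. Medians were 0.21 for macrophage (0 of 15; Apoe at -0.19 ± 0.43), 1.15 for erythroid (0 of 5; Hba-a1 at 1.15 ± 0.90) and 0.18 for FoxO targets (0 of 23; Sesn1 at 0.58 ± 0.23). They were 0.21 for PI3K subunits (0 of 9; Pik3r1 at 0.56 ± 0.24), -0.12 for cholesterol synthesis (0 of 21; Insig1 at 0.76 ± 0.22) and 0.05 for acute-phase and cachexia-linked factors (0 of 11; the haptoglobin gene Hp at 2.41 ± 0.86). Neutrophil granule and precursor genes had a median of -0.12 (0 of 8, 1 falling when adjusted over the list alone; Chil3 at -3.54 ± 1.01; adjusted p = 0.962 with an estimated correlation). Lysosome and phagocytosis genes had one of -0.05 (0 of 20, 1 rising when adjusted over the list alone, Cd36 at 2.70 ± 0.70; adjusted p = 0.976 with an estimated correlation). For oxidative phosphorylation (median 0.03, mean -0.05, 0 of 24) and chemoattractant receptors and integrins (median 0.10, mean -0.13, 0 of 17) the mean lay below 0 and the median and the test above it. The unfolded protein response (0 of 15; Calr at -0.52 ± 0.17) had a mean of 0.02 and a median just below 0.

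In the limma fit 143 genes rose and 216 fell of 16296 tested in tumours, and 3982 had an unadjusted p under 0.05, where 815 would be expected by chance. Of the 359, 283 were protein-coding, and 19 of the rises lay in a block of near-identical gene copies on chromosome 4 (41809083 to 42856771; Fam205a1 and its neighbours), with changes of 2.18 to 3.27 that cannot be counted as separate events. Camera with a preset correlation passed 23 of 40 lists, 17 higher and 6 lower, and with an estimated correlation 0. Fry passed 3, the heat shock, glycolysis and hypoxia, and islet lists. By the exact permutation test of list means 0 of 40 passed, with 9 at an unadjusted p under 0.05. The number of genes passing was 0 without treated tumour 4, 31 without treated tumour 2 and 121 without treated tumour 5. It was 179, 97, 112, 68 and 124 without vehicle tumours 1, 2, 3, 4 and 7, and 1690 without vehicle tumour 5. Without vehicle tumour 6, treated tumour 1 or treated tumour 3 it was 415, 422 or 466. All 24 genes with the largest changes, which were picked from these same libraries, kept their sign each time. Of them 0 stayed past the threshold without treated tumour 4, 3 without treated tumour 2 and 13 without treated tumour 5. All 24 did without vehicle tumour 5. With the acinar list mean as a covariate 0 genes passed in limma (2462 at an unadjusted p under 0.05). The dendritic cell call was lost without vehicle 2 (0.72), 3 (0.80) or 5 (0.83) or treated 3 (0.84), 4 (0.51) or 5 (0.75), and the monocyte call without vehicle 2 (0.29), 4 (0.26) or 5 (0.24) or treated 2 (0.28), 3 (0.25) or 5 (0.25). The ATF4 call was lost without vehicle 1 (-0.30) or 3 (-0.32) or treated 1 (-0.30), 2 (-0.37) or 4 (-0.33), the smooth muscle call without vehicle 5 (0.78) or treated 1 (0.34), and the plasma cell call without treated 1 (0.94).

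The PMN comparison asked whether granulocytes of the spleen differed after treatment of the animal. By camera with a preset correlation the clearest difference in treated PMN was in erythroid transcripts, which belong to red cell precursors and not to PMN. Hba-a1, an alpha-globin gene, averaged 10.49 ± 1.09 (SD, n = 3) in vehicle and 8.11 ± 0.74 (SD, n = 4) in treated libraries. Of 11 erythroid genes 0 passed over all genes and 6 fell when adjusted over the list alone, with a median change of -2.37 (adjusted p = 0.6249 with an estimated correlation; exact permutation p = 0.0571, two-sided). Cholesterol synthesis genes pointed the other way, with all 20 of 20 above 0 and a median of 0.38, among them Mvk at 0.98 ± 0.38 and Sc5d at 0.72 ± 0.25. Of them 0 were past the threshold by either adjustment (adjusted p = 0.6249 with an estimated correlation; exact permutation p = 0.143, two-sided). Ribosomal protein genes had a median of -0.14, with 0 of 28 past the threshold by either adjustment (adjusted p = 0.897 with an estimated correlation).

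No single PMN gene passed. Limma called 0 of 13968 genes, with 430 at an unadjusted p under 0.05 where 698 would be expected by chance. This number was 1046 without PMN vehicle library 3 and 989 with array quality weights, with 0 genes called each time. The genes with the smallest p were Pyroxd2 (1.03 ± 0.19), Zfpm1 (-1.28 ± 0.28), the scavenger receptor gene Cd36 (-2.68 ± 0.63), Abcb4 (-2.81 ± 0.67) and Camk4 (1.11 ± 0.27). They were followed by Cyth3 (-0.98 ± 0.24), Adgrl3 (-2.28 ± 0.58), Nxpe2 (-1.88 ± 0.49), Ighe (4.33 ± 1.14) and Bpgm (-0.86 ± 0.24). Pik3cd stood at 0.05 ± 0.20. The alarmin genes S100a8 and S100a9, at 14.05 and 13.68, held ranks that the shared distribution fixes, so no difference could be read there. Mature neutrophil, granule and precursor, and innate cytokine lists had medians of -0.01, 0.10 and -0.18 and 0 members past the threshold. Macrophage markers had a median of -0.39 with 0 of 13 past the threshold and 11 below 0 (C1qb at -1.46 ± 0.93, Apoe at -0.86 ± 0.60). Markers of other lymphoid and granulocytic cells stood at medians of 0.41 (T cell), -0.30 (B cell), 0.48 (NK and cytotoxic lymphocyte), 0.49 (mast cell and basophil) and -0.02 (eosinophil). In all 3 of 39 lists passed camera with a preset correlation. The ribosomal call was lost without PMN vehicle library 1 (-0.05), without PMN vehicle library 2 (-0.04) and without treated PMN library 3 (-0.06). The number of lists passing was 11 without PMN vehicle library 3, 7 without treated library 2 and 6 without treated library 4.

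In monocytes of treated against vehicle mice the MHC class II list had a median of 0.98, with Ciita, the master regulator of the class, at 1.43 ± 0.80 and 4.97 ± 1.23 (SD, n = 3) in vehicle against 6.40 ± 1.57 (SD, n = 4) in treated libraries. Of its genes 0 of 10 passed over all genes or when adjusted over the list alone (adjusted p = 0.82 with an estimated correlation; exact permutation p = 0.286, two-sided). The mature neutrophil list had a median of -0.21, with 12 of 16 genes below 0 and 0 past the threshold (camera, adjusted p = 0.111). Its means in vehicle libraries 1 to 3 were 8.49, 7.97 and 5.85, where those of MHC class II were 6.04, 5.83 and 7.56. In treated libraries 1 to 4 they were 7.71, 6.28, 7.53 and 6.56, against 5.88, 7.84, 7.29 and 8.39 for MHC class II. Erythroid genes had a median of -0.93 with 0 of 11 past the threshold by either adjustment (adjusted p = 0.82 with an estimated correlation). Medians were 0.34 for NF-kB feedback genes, with Nfkb2 at 0.50 ± 0.28, 0.25 for mitochondrially encoded genes, with mt-Nd3 at 0.80 ± 0.34, and 0.23 for cholesterol synthesis. They were 0.18 for the unfolded protein response, with Dnajb9 at 0.38 ± 0.16, -0.25 for cell cycle, with Mcm6 at -0.38 ± 0.27, and -0.22 for glycolysis and hypoxia, with the hexokinase gene Hk2 at -0.35 ± 0.12. These 6 lists passed camera with a preset correlation, had 0 members past the threshold by either adjustment, and had adjusted p = 0.82 with an estimated correlation.

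**Figure D3:**
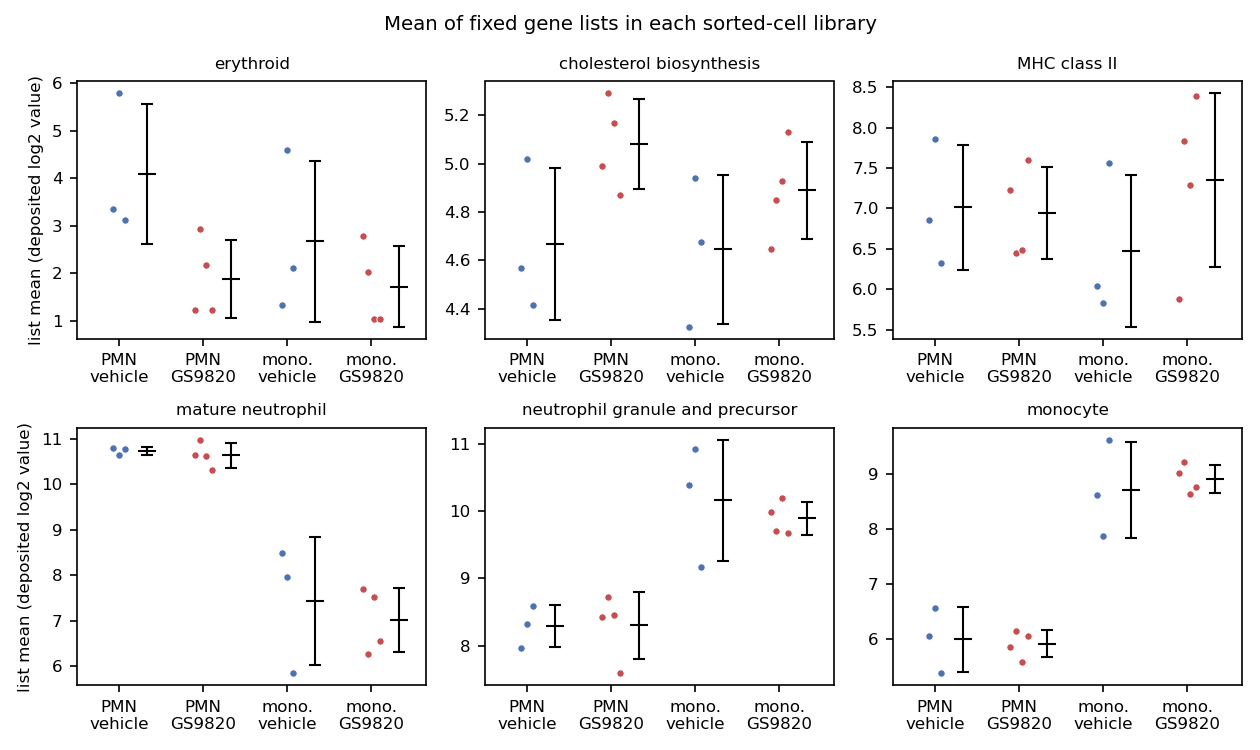
Mean deposited log2 value of 6 fixed gene lists in each sorted-cell library; points are libraries (3 vehicle and 4 GS9820 for PMN and for monocytes) and the bars beside them give the group mean ± SD. Neutrophil and monocyte markers separate the populations, whereas treated and vehicle libraries of 1 population overlap in most panels.

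For monocytes limma called 0 of 13968 genes, with 335 at an unadjusted p under 0.05 where 698 would be expected by chance. Without monocyte vehicle library 3 this number was 2982, again with 0 genes called (limma, smallest adjusted p = 0.0916). The genes with the smallest p were Ighv14-4 (-2.59 ± 0.58), the sialyltransferase gene St3gal2 (-0.50 ± 0.11), Slc36a1 (0.52 ± 0.12), Gpr146 (0.81 ± 0.20) and Ptprd (3.12 ± 0.78). Next came Sidt2 (0.45 ± 0.11), Qprt (-0.86 ± 0.23), the costimulatory ligand gene Icosl (0.52 ± 0.14), Oxr1 (-0.36 ± 0.10) and Trim30c (1.56 ± 0.43). Pik3cd stood at 0.20 ± 0.20. Markers of T cells, B cells, NK and cytotoxic lymphocytes, mast cells and basophils, and eosinophils stood at medians of -0.28, 0.09, -0.60, -0.39 and -0.54. Without monocyte vehicle library 2 the calls of MHC class II (0.62), erythroid (0.16), NF-kB feedback (0.02), glycolysis and hypoxia (-0.01), mitochondrially encoded (0.14) and cell cycle genes (0.12) were lost. The cholesterol call was lost without vehicle library 1 (0.09) and the cell cycle call too (-0.15), which was also lost without treated library 4 (-0.12). The unfolded protein response call was lost without vehicle library 3 (0.07), when 14 lists passed, and without treated library 2 (0.10).

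Monocytes and PMN of vehicle mice were compared to check the identity of the sorted populations and to give the scale of a difference between cell types. They parted along most of the monocyte and mature neutrophil markers. The matrix proteoglycan gene Vcan was 7.02 ± 0.98 higher in monocytes, at 7.71 ± 0.58 against 0.68 ± 2.36 (SD, n = 3 each). The coagulation factor gene F13a1 was higher by 6.22 ± 0.59, Fn1 (fibronectin) by 5.47 ± 0.70 and the chemokine receptor Ccr2 by 3.47 ± 0.50. In PMN the metalloreductase gene Steap4 was higher, with a difference of -8.13 ± 0.52, as were the chemokine receptors Cxcr1 (-7.76 ± 0.61) and Cxcr2 (-5.15 ± 0.72), the granulocyte colony-stimulating factor receptor Csf3r (-3.73 ± 0.19). The cytokine gene Il1b differed by -6.76 ± 0.61, at 5.04 ± 0.75 in monocytes and 11.80 ± 0.41 in PMN (SD, n = 3 each). In the monocyte list 11 of 14 genes were higher in monocytes, over all genes and when adjusted over the list alone, with a median of 1.98 (adjusted p = 0.45 with an estimated correlation). In the mature neutrophil list 13 of 16 were lower by both adjustments, with a median of -3.62 (adjusted p = 0.45 with an estimated correlation). Its members S100a8 and S100a9 still averaged 13.65 and 13.25 in vehicle monocytes, against 14.05 and 13.68 in PMN.

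Of 15 neutrophil granule and precursor genes 8 were higher in monocytes by either adjustment, among them the azurophil granule genes Elane (5.56 ± 0.89), Prtn3 (5.32 ± 0.79), Mpo (5.08 ± 0.73) and Ctsg (4.76 ± 0.89), while Ngp (-0.27 ± 0.31) and Ltf (-0.78 ± 0.42), of other granules, did not pass. This list did not pass camera (adjusted p = 0.139; adjusted p = 0.741 with an estimated correlation; exact permutation p = 0.1, two-sided). All 32 cell cycle genes (median 2.79, Top2a 3.32 ± 0.33) and all 28 ribosomal protein genes (median 1.88) were higher by either adjustment (adjusted p = 0.45 and 0.377 with an estimated correlation). So were 23 of 24 oxidative phosphorylation genes (mean change 0.97; adjusted p = 0.331 with an estimated correlation) by either adjustment. Also higher were 11 of 13 mitochondrially encoded genes (13 when adjusted over the list alone, median 1.44; adjusted p = 0.536 with an estimated correlation) and 10 of 15 genes of the unfolded protein response (10 when adjusted over the list alone, median 0.92; adjusted p = 0.64 with an estimated correlation). Lower in monocytes by either adjustment were 10 of 13 innate cytokines and mediators (median -2.91, Il1rn -3.38 ± 0.35 and the inflammasome gene Nlrp3 -2.91 ± 0.42; adjusted p = 0.0905 with an estimated correlation) and 8 of 12 suppressor effectors (median -1.44, Arg2 -6.10 ± 0.32; adjusted p = 0.0905 with an estimated correlation). The same held for 13 of 17 immediate early genes (median -1.73, Dusp1 -5.39 ± 0.44; adjusted p = 0.331 with an estimated correlation) and 11 of 17 chemoattractant receptors and integrins (median -1.03, Selplg -2.37 ± 0.21; adjusted p = 0.27 with an estimated correlation). The FoxO list had 14 of 21 lower over all genes and 15 when adjusted over the list alone (median -1.39; adjusted p = 0.331 with an estimated correlation). B cell markers were lower in monocytes in 14 of 15 genes by either adjustment (median -1.82, Ms4a1 -2.30 ± 0.42; adjusted p = 0.45 with an estimated correlation). Also lower were 4 of 6 adipocyte genes (median -2.03) and 5 of 8 matrix proteases and inhibitors (median -2.36), by either adjustment (adjusted p = 0.117 and 0.252 with an estimated correlation). Pik3cg (-0.66 ± 0.16) and Pik3ca (-0.60 ± 0.16) were lower in monocytes, while Pik3cd (-0.49 ± 0.22; limma, adjusted p = 0.0702) and Pik3cb (-0.24 ± 0.27) did not pass.

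**Figure D4:**
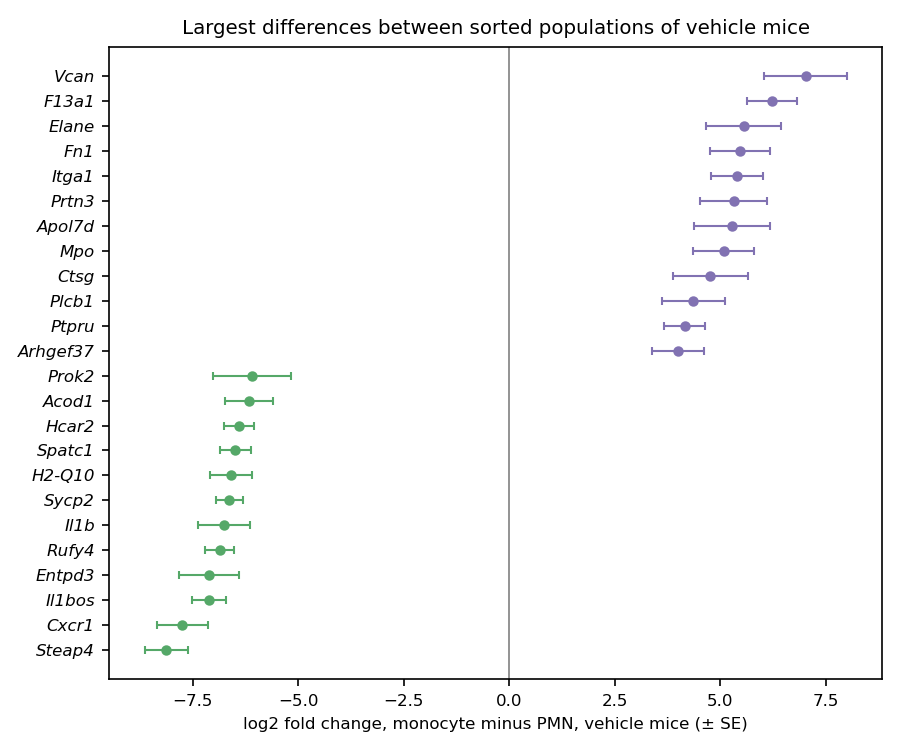
The 12 largest differences in each direction between monocytes and PMN of vehicle mice among named genes past the threshold; the x axis gives the log2 fold change, monocyte minus PMN, each point is the fitted difference and each bar its SE. The differences range from -8.13 for Steap4 to 7.02 for Vcan.

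Of 13968 genes 4586 were higher and 3804 lower in monocytes than in PMN (limma). The remaining large differences were higher for Itga1 (5.40 ± 0.62), Apol7d (5.28 ± 0.89, which overlaps Fn1), Plcb1 (4.36 ± 0.74), Ptpru (4.16 ± 0.48) and Arhgef37 (4.00 ± 0.62). They were lower for Il1bos (-7.12 ± 0.40, the opposite strand of Il1b), Entpd3 (-7.11 ± 0.71), Rufy4 (-6.87 ± 0.35), Sycp2 (-6.64 ± 0.33) and H2-Q10 (-6.60 ± 0.50). The list ends with Spatc1 (-6.50 ± 0.37), the nicotinic acid receptor Hcar2 (-6.41 ± 0.36), Acod1 (-6.18 ± 0.57) and Prok2 (-6.11 ± 0.92). In camera with a preset correlation 15 of 39 lists passed and with an estimated correlation 0, and 25 passed with fry. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1.

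Whether the inhibitor acted differently in the 2 populations was tested as the difference of their treatment effects. Hba-a1 showed a difference of 1.38 ± 0.99 (monocyte effect minus PMN effect) and Ciita one of 1.40 ± 1.13, and neither passed. Limma called 0 of 13968 genes for this difference, with 269 at an unadjusted p under 0.05 where 698 would be expected by chance, and Pik3cd stood at 0.15 ± 0.29. The number at an unadjusted p under 0.05 was 2147 without monocyte vehicle library 3 and 854 without PMN vehicle library 3, with 0 genes called each time. By camera with a preset correlation 12 of 39 lists differed, the erythroid (median 1.38), MHC class II (0.87) and cell cycle lists (-0.38) among them, each with 0 members past the threshold by either adjustment and each with adjusted p = 0.749 with an estimated correlation.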

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

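Chosen as tests only after the results were seen were the clock genes and their opposite arm, the islet hormones, the ductal median and the ductal list with the islet list mean as a covariate, while the splits and the other tests with covariates were written down before their own results.

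Glycolysis and hypoxia genes were lower in treated tumours, by -1.15 ± 0.26 in the list mean. Less carcinoma epithelium would lower ductal genes as well; their median change was 1.02 and the ductal minus the glycolysis list mean was 2.11 ± 0.95, and 1.502 ± 0.66 without vehicle tumour 1, where the ductal list mean went from 0.96 ± 0.86 to 0.38 ± 0.56. With the islet list mean as a covariate, however, the list ductal and carcinoma epithelium in tumours stood at -1.18, so this explanation stays open. More normal pancreas in the treated pieces could lower the list. With the acinar and islet list means as covariates the effect stayed below 0, at -0.94 ± 0.43. By the rule set beforehand, an effect more than 2 SE below 0 was to count against this explanation, and the value just met it. In a fit of 12 libraries with 2 covariates this margin is too small to decide, so this explanation as the whole cause stays open as well.

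Islet genes were higher in treated tumours, by 3.49 ± 0.89 in the list mean. If pieces with more exocrine tissue had carried islets along, the effect would shrink with the acinar list mean as a covariate, and it was 2.995 ± 0.98, which argues against that as the whole cause. More islet tissue in the treated pieces stays open: 6 of 6 hormone genes had a positive change (Gcg 5.57, Ins1 5.38, Iapp 4.91, Ins2 4.70, Ppy 4.69 and Sst 4.45), but they belong to the list already seen to be higher and cannot test it. Whether such tissue was taken with the tumour or belongs to it cannot be read from these values.

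Of 16 genes of the circadian clock, 5 rose in treated tumours (limma): Dbp by 2.39 ± 0.42, Per3 by 1.54 ± 0.32, Nr1d1 by 1.52 ± 0.29, Nr1d2 by 1.24 ± 0.19 and Tef by 1.18 ± 0.25. The other 11 did not pass: Hlf (2.06 ± 0.77), Per2 (0.65 ± 0.39), Cry2 (0.27 ± 0.29), Per1 (0.19 ± 0.38), Ciart (-0.03 ± 0.38), Bhlhe41 (-0.35 ± 0.31), Nfil3 (-1.43 ± 0.42), Cry1 (-0.99 ± 0.37), Arntl (-0.98 ± 0.27), Npas2 (-0.43 ± 0.44) and Clock (-0.02 ± 0.13). A shift of clock phase, such as another time of day at harvest, would lower the last 5, whose mean differed by -0.77 ± 0.17, but all were chosen after the values were seen, so this cannot test it and it stays open. More normal pancreas could also shift these genes, but with acinar and islet list means as covariates the difference of the rising group (with Hlf) minus these 5 was 2.67 ± 0.49, against 2.43 ± 0.33 without, which argues against it as the whole cause.

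Of 792 possible splits of the tumours into groups of the same sizes, 100 were run. Of these 100, 3, the real one included, gave at least as many genes as the real 359. This makes chance less likely but does not exclude it, and the highest other split gave 2185. That split set vehicle tumours 1, 2, 3, 4 and 7 against the treated tumours with vehicle tumours 5 and 6. It points to a structure of the samples, which overlaps with the treatment since 10 of the 12 libraries lie on their real side. For tumour lists 5 of 100 splits gave at least the real 23 (highest other 24), so chance cannot be excluded. Camera with the preset correlation passed at least 1 list in all 99 other splits, with a median of 15. For lists in PMN 35 of 35 splits reached the real 3 (highest other 15) and for lists in monocytes 30 of 35 the real 8 (highest other 17), so chance cannot be excluded there either. At least 1 list passed in all 34 other splits of each, with medians of 8 in PMN and 11 in monocytes. Where the real count of genes was 0, every split reaches it and nothing is tested: 35 of 35 in PMN (highest other 4), 35 of 35 in monocytes (highest other 1448) and 100 of 100 for the difference of effects (highest other 1321). The last 2 of these highest counts point to a structure of the samples. The monocyte split with 1448 genes set vehicle libraries 1 and 2 and treated libraries 1 and 3 against the others. Mature neutrophil list means were 7.53 to 8.49 in this group and 5.85 to 6.56 in the others. Those of MHC class II were 5.83 to 7.29 and 7.56 to 8.39. This structure cuts across the treatment, and its cause was not tested. For monocytes against PMN 1 of 10 splits gave the real 8390 (highest other 1), and the splits are too few for a share under 0.05.

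Single libraries were compared with the rest of their group for lists and named genes, a gap test that by chance picks out about 1 in 20 groups: of 310 groups 23 held such a library, where 16 would be expected. The vehicle groups of PMN and of monocytes, with 3 libraries each, were too small for this test and were not checked. For each such library the value is given with the nearest other of its group. Vehicle tumour 5 stood apart in mature neutrophil genes (5.46, nearest 3.79), mitochondrially encoded genes (9.92, nearest 8.72), cell cycle genes (3.98, nearest 5.30) and Pbp2 (0.46, nearest 1.91). Vehicle tumour 1 stood apart in macrophage (7.45, nearest 6.03), ductal (3.73, nearest 6.71) and lysosome genes (7.58, nearest 6.77), and vehicle tumour 3 in fatty acid oxidation (4.27, nearest 4.66). Treated tumour 1 stood apart in smooth muscle (6.29, nearest 4.08) and oxidative phosphorylation (7.81, nearest 6.72), and treated tumour 3 in granule and precursor (5.02, nearest 3.91) and ductal genes (6.39, nearest 8.30). In PMN treated library 4 stood apart in mast cell and basophil (2.39, nearest 3.58), innate cytokine (5.69, nearest 6.07) and heat shock genes (6.24, nearest 5.84) and in Ctsg (0.12, nearest 3.22), treated library 2 in Pik3cd (8.65, nearest 9.05) and treated library 1 in Spatc1 (6.27, nearest 5.94). In monocytes treated library 1 stood apart in mast cell and basophil genes (2.01, nearest 1.52) and Oxr1 (7.45, nearest 7.57), treated library 3 in ductal genes (1.74, nearest 1.46) and treated library 4 in innate cytokines (3.42, nearest 3.63) and Prtn3 (8.21, nearest 8.99).

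The treatment effect of 12 lists differed between monocytes and PMN by camera with a preset correlation, and these are given because a list then moves in 1 population and less or oppositely in the other. Median differences (monocyte minus PMN) were 1.38 for erythroid, 0.87 for MHC class II, 0.79 for macrophage, 0.42 for B cell, 0.37 for NF-kB feedback, 0.34 for lysosome, 0.30 for mitochondrially encoded, 0.20 for unfolded protein response and 0.12 for ribosomal protein genes, and -1.23 for NK and cytotoxic lymphocyte, -0.72 for T cell and -0.38 for cell cycle genes. With an estimated correlation 0 of these lists passed (lowest adjusted p = 0.749).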

How the results depend on the processing

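The islet covariate, the removal of both tumours least correlated with their groups, the protein-coding and chromosome 4 restrictions and the list fits with covariates were chosen only after the results were seen.

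The count of 359 tumour genes was 2764 with array quality weights, 0 with the acinar list mean as a covariate (2462 at an unadjusted p under 0.05) and 0 with the islet list mean as a covariate (611). It was 280 without both tumours least correlated with their groups. Leaving out 1 tumour gave 0 (treated 4) to 1690 (vehicle 5) genes. In between lay vehicle 1 with 179, vehicle 2 with 97, vehicle 3 with 112, vehicle 4 with 68, vehicle 7 with 124, treated 2 with 31 and treated 5 with 121. Vehicle 6 with 415, treated 1 with 422 and treated 3 with 466 lay above the 359. The cause was not tested. With the acinar covariate Pyy went from 5.20 ± 1.16 to 4.76 ± 1.31 and Pfkl from -1.21 ± 0.23 to -1.16 ± 0.26, and neither passed. With the islet covariate Pyy stood at 0.26 ± 0.57. The filters, log2 of the value plus 1, the normalizations, the variance models and the restrictions of genes kept the count within 1.5 times.

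Of tumour lists 23 passed with the preset correlation, 0 with an estimated correlation, 3 with fry, and 14 with the islet list mean as a covariate. Those passing fry were heat shock (fry, adjusted p = 0.0162), glycolysis and hypoxia (fry, adjusted p = 0.0205) and islet (fry, adjusted p = 0.0447). Leaving out 1 tumour gave 20 to 25 with the preset correlation. With the islet covariate the direction turned for Ppy in tumours (-0.0432) and for the lists MHC class II (-0.55), B cell (-0.38), ductal and carcinoma epithelium (-1.18), pancreatic islet (-0.19) and ATF4 (0.0356). For the unfolded protein response the test turned from up to down, and its median, just below 0 before, was -0.31. The list NF-kB feedback targets in tumours turned as well (-0.0676). With the acinar covariate the acinar list itself turned (-0.14). For this list, and for the islet list and its member Ppy with the islet covariate, the turn is built in, as the list's own mean was in the fit. Oxidative phosphorylation turned without both least correlated tumours (-0.21), and over single tumours left out it ran from -0.26 (without treated 1) to 0.11 (without treated 2); the cause was not tested.

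In PMN lists 0 passed with an estimated correlation and 0 with fry, and leaving out 1 library gave 3 to 11 (vehicle 3: 11; treated 2: 7; treated 4: 6). In monocyte lists 0 passed with an estimated correlation and 0 with fry, and leaving out 1 library gave 6 (vehicle 2) to 14 (vehicle 3). Directions turned without single libraries, given as the lowest to the highest value: NK and cytotoxic lymphocyte genes in PMN -1.12 (without vehicle 2) to 1.56 (without vehicle 3), Xbp1 in monocytes against PMN -0.49 (without PMN vehicle 3) to 0.55 (without PMN vehicle 2). In monocytes these ranges were T cell -1.002 (without vehicle 2) to 0.45 (without vehicle 1) and erythroid -1.68 (without vehicle 1) to 0.16 (without vehicle 2). They were interferon-stimulated genes -0.27 (without vehicle 2) to 0.97 (without vehicle 3) and cell cycle -0.71 (without vehicle 3) to 0.12 (without vehicle 2); the cause was not tested. The counts of 0 genes in PMN, in monocytes and for the difference of effects stayed 0 throughout, although their numbers at an unadjusted p under 0.05 moved with single libraries (without vehicle library 3 of PMN 1046 in PMN, and without vehicle library 3 of monocytes 2982 in monocytes and 2147 for the difference). The count for monocytes against PMN stayed within 1.5 times.

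Replicate numbers were tried as a block. Libraries of the same number did not deviate together in every pair: correlations were over 0.1 in 2 of 5 tumour pairs, 0 of 3 PMN pairs, 1 of 3 monocyte pairs and 4 of 7 pairs across cell types, and the own number correlated best in 2, 1, 1 and 5 of them, so the numbers were not taken as pairing. The block was fitted on tumours numbered 1 to 5, without vehicle tumours 6 and 7. Then 171 tumour genes passed, 142 higher and 29 lower against 143 and 216 in the main fit. Of the 171, 73 were among the 359. Leaving out vehicle tumour 7 alone gave 124 genes. The part of the block cannot be told apart from that of the missing libraries. For the treatment effects in PMN and in monocytes the block left out treated library 4. In PMN 12 lists passed with the block, against 3 in the main fit and 6 when only treated library 4 was left out. The other counts moved by less than 1.5 times. The sex of the mouse as a covariate was not run, since genes of chromosomes X and Y were not analysed here.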

Other observations

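The complement genes and the regions below were chosen only after the results were seen.

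Among genes of the complement system, the terminal components C7 and C6 rose in treated tumours by 2.58 ± 0.60 and 2.14 ± 0.47, C4a by 2.37 ± 0.54 and the protease genes C1ra and C1rb by 2.03 ± 0.40 and 1.85 ± 0.37 (limma, adjusted p from 0.0301 to 0.0463). C3 stood at 2.39, C4b at 2.29, C1s1 at 2.19 and C2 at 1.73 without passing.

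Of the genes that fell in tumours 33 lay on chromosome 8, where 11.5 would be expected from its share of the genes tested. This was the largest excess of all chromosomes and was picked after the counts were seen, and it was not tested. The median deviation of its genes from their mean over all tumours was 0.08, 0.21, 0.15, 0.40, -0.11, -0.08 and 0.17 in vehicle tumours 1 to 7 and -0.27 to -0.10 in treated tumours. The sign was not particular to chromosome 8: the medians of chromosomes 2, 3, 5, 12, 13, 18 and 19 also lay below 0 in every treated tumour. In chromosomes 3, 12 and 13, however, the highest treated value was -0.0015, -0.0004 and -0.0016. Chromosome 8 had the lowest median change of protein-coding genes (-0.245), followed by chromosome 18 (-0.225). Vehicle tumours 5 and 6, below 0 for chromosome 8, were those set with the treated tumours in the split with 2185 genes. The copy number of these tumours was not analysed here.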
